A study of Mus musculus with 12 samples.

How the data were processed

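Gene expression was measured by RNA sequencing in 12 libraries of sorted mouse osteoclast precursors, 4 groups of 3, cultured for 3 days by the titles with M-CSF alone or with M-CSF and 30 ng/ml RANKL. Per the labels' protocols, RNA was extracted with an RNeasy Plus kit and libraries were made with a stranded poly(A) mRNA kit. The submitters' processing notes name fastp, STAR 2.7.3a, edgeR and the mouse build mm10. The counting program, its strand setting and the annotation release are not given in the sources used here, so overlapping and antisense genes, and genes that share reads with close copies, are uncertain.

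The authors deposited whole-number read counts for 23863 genes, a filtered count table of 10255 of those genes, the log2 CPM of the filtered genes and a table of their own comparisons. The counts of the 10255 filtered genes were equal to those of the full count file, and each of these genes reached 1 CPM in at least 6 libraries. The deposited log2 CPM matched the counts with normalization factors between 0.975 and 1.03. The authors' deposited table gives log2 fold changes and p-values with false discovery rates for 5 comparisons, and is quoted only where it is named. Here 0 columns of values were left without a sample and 0 genes without a name.

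Everything else was computed here from the full count table in R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and data.table version 1.17.8. Genes were kept by filterByExpr on the 4 groups with its minimum count of 10, which left 13236 genes, 425 of them on the X and 7 on the Y chromosome. Libraries were scaled by TMM, and 1 quasi-likelihood model with a mean per group was fitted with edgeR to all 12 libraries, so that all groups share 1 estimate of the spread. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. The comparisons were female against male in M-CSF, female against male in M-CSF+RANKL, M-CSF+RANKL against M-CSF in each sex, and the difference of these responses. The comparison of the sexes over the mean of both treatments was added after the data were seen. Gene IDs were matched to the GENCODE vM21 annotation, which held 23855 of the 23863.

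Gene groups were 34 lists fixed before the data were examined, of which 30 were tested with camera at a preset inter-gene correlation of 0.01, for lists with at least 3 tested genes. The erythroid list had 0 tested genes and the stromal and eosinophil lists 2 each, and the list of sex label genes was kept out of these tests. The same tests were repeated with an estimated correlation and with fry. For lists, the counts "over the list alone" adjust over that list's tested genes only.

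Named genes were chosen by a rule fixed before the data were examined. It takes the 10 largest rises and 10 largest falls among called genes whose 3 libraries of one group all lay above the other's, with a mean of at least 5 CPM in the higher group. It adds up to 4 called members of each list with the largest change, or 2 members with the highest mean CPM where none was called, and a fixed set of sex chromosome, osteoclast and cytokine genes. Genes outside it are said to be chosen after their values were seen. Some genes that the rule names are not reported here. Folds against a group without counts use a floor of 3 counts over the group, and those against a few counts carry a 95% counting interval, both covering counting error only.

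The depth was 10646697 to 15983769 counts per library. Reads of mitochondrial genes made up 1.99 ± 0.489% of counts in female M-CSF, 1.84 ± 0.169% in male M-CSF, 3.33 ± 0.331% in female M-CSF+RANKL and 3.76 ± 0.114% in male M-CSF+RANKL (SD, n = 3). The largest gene of a library took 1.32 to 1.76% of its counts. Replicates of a group differed by far more than sampling noise, with a chi-square per degree of freedom of 11.2 to 33.7 over genes with at least 20 counts, so none was taken for a repeat deposit. Within a sex, libraries of the 2 treatments with the same replicate number deviated together from their group means, with correlations of 0.302 to 0.706 against -0.618 to -0.00958 for other numbers, over genes above a log2 CPM of 3. These numbers come from the titles, and by this check they pair the libraries within a sex.

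The tests were run on simulated counts with 200 genes changed in a group of 3 libraries, and in both female groups for the mean of both treatments. Before planting, each gene had the same mean in all 4 groups, pooled over the 12 libraries, so the simulation held no RANKL effect. Of planted 2-fold changes, 73.1% were found for the sexes in M-CSF, 66.7% for the sexes in M-CSF+RANKL, 66.7% and 77.6% for RANKL in females and males, 47.0% for the difference of responses and 77.3% for the mean of both treatments. Of planted 1.5-fold changes, 24.2%, 18.8%, 28.1%, 30.3%, 4.69% and 55.4% were found in the same order. Among the unchanged genes 10, 7, 7, 12, 10 and 12 were called in the same order. With 1.5-fold changes planted in lists, camera called 3 of 3 such lists and 0 of 27 unchanged lists in each of these simulated comparisons. Each gene and library was drawn independently, without inter-gene correlation, so the 0 of 27 does not carry over to the real lists. In splits of the real libraries that mix the sexes, camera called a median of 5 lists in M-CSF and 9 in M-CSF+RANKL. Real libraries of the same sex and replicate number moved together. The shares found for the mean of both treatments may therefore be too high.

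Alternatives fixed before the data were examined were DESeq2 size factors, the DESeq2 Wald test, no low count filter, only the 6 libraries compared, the replicate number as a block, each library left out in turn, an added 2-fold threshold, and counts without Xist, Tsix, Ddx3y, Eif2s3y, Kdm5d and Uty. Chosen after seeing the data were the genes of the authors' filtered table and, for the mean of both treatments, its whole set of alternatives, with counts summed over the treatments and both libraries of a sex and replicate number left out.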

Results

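RNA was sequenced from osteoclast precursors of mouse bone marrow, sorted by flow cytometry as cells without the B cell marker CD45R and the T cell marker CD3, with little or no CD11b and with the M-CSF receptor CD115. The mice carried 1 conditional (floxed) allele of Runx1, a transcription factor gene of blood cell development. The sample titles also carry the tag WT. Sorted cells of each sex were cultured with the macrophage growth factor M-CSF alone or with M-CSF and 30 ng/ml RANKL, the cytokine that turns such precursors into osteoclasts, the cells that resorb bone. The sample titles and the treatment protocol give 3 days of culture while the growth protocol gives another duration, so the day of harvest is taken here from the titles. There were 4 groups of 3 libraries each: female M-CSF, male M-CSF, female M-CSF+RANKL and male M-CSF+RANKL. The libraries held 10646697 to 12970278 counts in female M-CSF, 10814687 to 14113420 in male M-CSF, 14303174 to 15246430 in female M-CSF+RANKL and 14379792 to 15983769 in male M-CSF+RANKL. The labels do not say whether the 3 libraries of a group came from separate mice, so p-values measure the spread between these samples, which may be technical. The first principal component of log2 CPM, counts scaled to a common library size, carried 84.7% of the variance and parted the libraries with RANKL from those without. The labels of sex were met by the sex chromosome genes in all 12 libraries. Xist, the RNA that silences an X chromosome, was at 535 ± 70.2 CPM in female and 0.116 ± 0.145 CPM in male M-CSF libraries (SD, n = 3). The Y gene Eif2s3y had 0 counts in all 6 female libraries.

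What RANKL changed in female precursors was the first question. The genes of the resorbing osteoclast rose from near silence. Acp5, the tartrate-resistant acid phosphatase used to stain osteoclasts, went from 2.35 ± 0.746 to 4619 ± 730 CPM in females (SD, n = 3), a log2 fold change of 10.93 ± 0.24 (SE). Ctsk, the cathepsin that digests bone collagen, rose by 12.32 ± 0.49 on the log2 scale, and Mmp9, a gelatinase of osteoclasts, rose by 12.20 ± 0.65. Dcstamp, needed for the fusion of precursors into multinucleated cells, rose by 8.05 ± 0.20, and Nfatc1, the transcription factor at the head of the osteoclast programme, rose by 3.69 ± 0.12 from 59.7 ± 2.55 CPM. At the same time macrophage genes collapsed: Mrc1, the mannose receptor, fell by 5.86 ± 0.45 and the complement gene C1qa fell by 5.27 ± 0.36 on the log2 scale. In all, 6875 of 13236 tested genes changed in females, 3549 up and 3326 down, and 3442 of them by at least 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05).

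**Figure D1:**
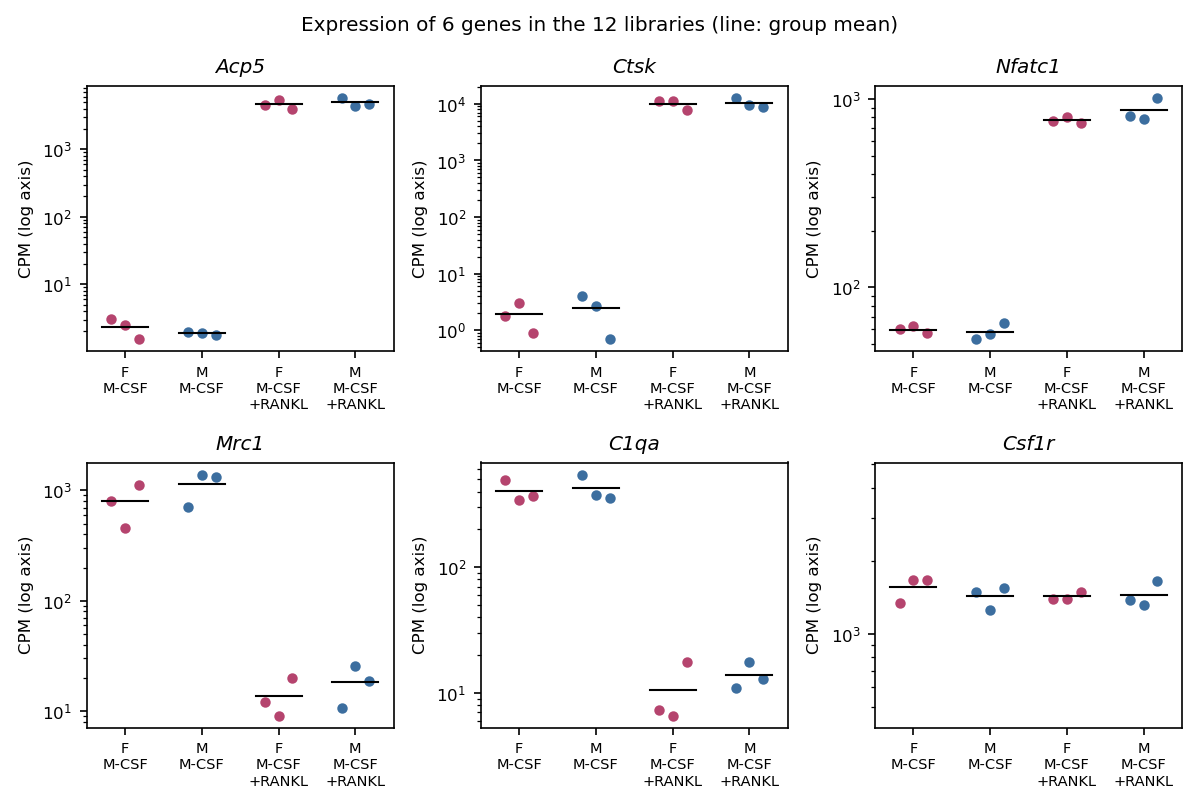
CPM on a log axis of Acp5, Ctsk, Nfatc1, Mrc1, C1qa and Csf1r in the 3 libraries (points) of each of the 4 groups, with F for female and M for male, and lines for the group means. Acp5, Ctsk and Nfatc1 lie higher and Mrc1 and C1qa lower in every library with RANKL, while Csf1r stays between group means of 1425 and 1558 CPM.

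Several osteoclast genes had no counts at all without RANKL, so their folds are lower bounds taken against a floor of 3 counts over the group. In females Calcr, the calcitonin receptor, was at least 630.4-fold higher with RANKL, Mt3, a metallothionein, at least 3153-fold, Steap4, a metalloreductase, at least 642-fold and Rufy4 at least 2052-fold. Oscar, an osteoclast receptor for collagen, had 1 count in the female M-CSF group and a ratio of 7442 (95% counting interval 1335 to 293990.0). All 27 members of the osteoclast list rose in females and the same number in males, 27 and 27 of them also when adjusted over the list alone. The median log2 fold change was 8.19 in females and 8.18 in males, the same with members lacking counts at their bounds. The camera test of this list had an adjusted p of 1.17e-83 in females and 2.81e-76 in males, and adjusted p = 0.000413 and 0.00106 with an estimated correlation. Among its members were Src, the kinase needed for the ruffled border, with a log2 fold change of 8.74 in females and 9.72 in males, and Itgb3, a subunit of the integrin by which osteoclasts grip bone, with 8.19 and 8.12. Tnfrsf11a, which encodes the RANKL receptor, rose by 1.22 ± 0.11 in females and 1.25 ± 0.11 in males. Csf1r, the gene of the M-CSF receptor used for sorting, did not pass in either sex, with log2 fold changes of -0.13 ± 0.12 and 0.02 ± 0.12 (adjusted p 0.414 and 0.903).

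Genes that make the acid and the adhesion machinery of the osteoclast rose as groups. Of 15 vacuolar proton pump genes, 13 rose and 1 fell in each sex, also when adjusted over the list alone, with a median log2 fold change of 1.46 in females and 1.61 in males (camera adjusted p 1.63e-07 and 9.33e-08). These calls were lost with adjusted p = 0.137 and 0.122 with an estimated correlation. Atp6v1b2 rose by 2.76 in females and 2.81 in males and Atp6v1d by 2.40 and 2.59, both subunits of the ATP-hydrolysing part, while Atp6v0a1, a membrane subunit, fell by 2.49 and 2.89. In the podosome and integrin list 13 of 21 rose and 4 fell in each sex, with the same counts over the list alone. Its camera adjusted p was 4.39e-08 in females and 5.91e-08 in males, against adjusted p = 0.106 and 0.122 with an estimated correlation; the actin regulator Cttn rose by 6.34 and 6.57. All 31 mitochondrial respiration genes rose in each sex, 31 also over the list alone, with a median of 1.13 in females and 1.32 in males (camera adjusted p 2.43e-14 and 1.11e-16; adjusted p = 0.256 and 0.194 with an estimated correlation). The citrate cycle enzyme gene Mdh2 rose by 1.61 in females and 1.81 in males, and Cyc1, a subunit of respiratory complex III, by 1.60 and 1.95.

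The NF-kB list, genes of the pathway through which the RANKL receptor signals, had 15 of 23 members up and 1 down in females and 15 up and 2 down in males, and 16 up over the list alone in each. Its camera adjusted p was 3.45e-07 in females and 5.29e-07 in males, and adjusted p = 0.0473 and 0.0487 with an estimated correlation. Traf1, an adaptor of TNF receptors, rose by 5.35 in females and 5.53 in males, Nfkb2 by 2.27 and 2.31 and the inhibitor gene Nfkbie by 2.16 and 2.31. Of 12 bone coupling factors, secreted or surface proteins by which osteoclasts act on bone-forming cells, 8 rose and 3 fell in females and 9 rose and 2 fell in males. Over the list alone it was 8 up and 3 down in females and 9 up and 3 down in males (camera adjusted p 0.000944 and 0.000955; adjusted p = 0.125 and 0.122 with an estimated correlation). Sphk1, a kinase that makes sphingosine 1-phosphate, had 1 count in female M-CSF libraries, a ratio of 780.2 (95% counting interval 139.7 to 30847), and was at least 339-fold higher in males. Cthrc1, a secreted collagen triple helix protein, was at least 47.1-fold higher in females and at least 47.7-fold in males, and the cytokine gene Lif had ratios of 479.8 (133 to 3967) and 176 (85.1 to 438). Igf1, which encodes a growth factor and is on the same list, fell by 6.01 and 6.58.

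Macrophage and innate immune genes fell with RANKL in both sexes. Of 24 macrophage and monocyte identity genes 18 fell and 0 rose in females and 19 fell and 0 rose in males, with 19 down over the list alone in each. The median log2 fold change was -1.99 in females and -2.43 in males, with camera adjusted p 8.51e-12 and 5.35e-12, and adjusted p = 0.0523 and 0.101 with an estimated correlation. Cd163, a haemoglobin scavenger receptor, fell by 4.52 and 4.94, and Fcgr3, an Fc receptor, by 4.04 and 4.49. Irf8, a repressor of osteoclast formation, fell by 2.56 ± 0.16 in females and 3.17 ± 0.17 in males. Of 13 osteoclastogenesis repressors 7 fell and 2 rose in each sex, also over the list alone, and the list did not pass (camera adjusted p 0.11 and 0.0739; 0.0355 in males with the replicate number as a block). Id1, an inhibitor of DNA-binding factors, fell by 2.96 and 2.79. In the complement and Fc receptor list 13 of 17 genes fell in each sex, 13 and 14 over the list alone, and 2 rose in females and 3 in males. Against the list's direction, Itgax, an integrin subunit of myeloid cells, rose by 2.42 and 2.12. That list had camera adjusted p 9.8e-08 and 1.35e-07, and adjusted p = 0.0873 and 0.122 with an estimated correlation. In the innate sensing list 20 of 30 genes fell and 3 rose in females and 23 fell and 3 rose in males. Over the list alone it was 4 up and 20 down in females and 3 up and 23 down in males (camera adjusted p 0.000101 and 6.79e-06; adjusted p = 0.284 and 0.202 with an estimated correlation). The RNA-sensing receptor genes Tlr7, Tlr8 and Tlr13, all on the X chromosome, had log2 fold changes of -3.78, -3.70 and -3.38 in females and -4.50, -4.36 and -3.93 in males, and the inflammasome gene Nlrp3 had -2.31 and -2.95.

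Chemokine genes were among the largest losses. Ccl7, Ccl2 and Pf4, chemokines of monocytes and platelets, had log2 fold changes of -7.62, -5.61 and -5.76 in females and -7.31, -5.81 and -5.24 in males, and Tnf fell by 1.76 ± 0.28 and 1.73 ± 0.29. Il1b, the gene of interleukin 1 beta, rose by 1.25 ± 0.31 in females and 1.44 ± 0.34 in males. Il6, an interleukin gene named in advance, was not tested, with 13 counts over the 12 libraries. Of 26 tested inflammatory cytokine and chemokine genes 14 fell and 4 rose in females and 13 fell and 4 rose in males, with the same counts over the list alone (camera adjusted p 0.000723 and 0.00091; adjusted p = 0.397 and 0.399 with an estimated correlation). Of 35 interferon-stimulated genes 17 fell and 3 rose in females and 29 fell and 2 rose in males, 18 and 31 down over the list alone. Its camera adjusted p was 0.0208 in females and 0.000194 in males, and adjusted p = 0.777 and 0.650 with an estimated correlation; without female M-CSF+RANKL replicate 2 the female call was lost (adjusted p 0.0562). Male M-CSF replicate 2 stood at a mean log2 CPM of 5.12 over the list, against 3.45 to 4.10 in the other 5 M-CSF libraries. Without it the male median of -1.84 was -1.22 (adjusted p 0.000283). Oasl2, an antiviral gene, fell by 1.80 ± 0.47 and 3.11 ± 0.50, and Gbp7, a guanylate-binding protein gene of the same list, rose by 2.97 and 2.30.

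Proliferation, sterol synthesis and lysosomal genes also fell. Of 32 cell division genes 31 fell in females and 30 in males, 31 over the list alone in each, with medians of -0.87 and -0.91 (camera adjusted p 1.29e-09 and 1.31e-09; adjusted p = 0.125 and 0.122 with an estimated correlation). Pcna, the sliding clamp of DNA replication, had log2 fold changes of -1.78 and -1.94, and Kif23, a kinesin of cell division, had -1.27 and -1.54. Of 18 cholesterol synthesis genes 16 fell in females and 17 in males, 17 over the list alone in each (camera adjusted p 3.89e-06 and 9.55e-06; adjusted p = 0.391 and 0.399 with an estimated correlation). Among them Fdft1, squalene synthase, had -2.06 and -2.01. Of 22 lysosome genes 11 fell and 5 rose in females and 12 fell and 6 rose in males, with 12 down over the list alone in each (camera adjusted p 0.000723 and 0.000955; adjusted p = 0.309 and 0.340 with an estimated correlation). Cathepsins other than Ctsk were among these, with log2 fold changes of -2.59 for Ctsl in females and of -2.26 and -2.41 for Ctsb in females and males. Runx1, which carries the floxed allele, fell by 0.65 ± 0.11 in females and 0.70 ± 0.11 in males, from 64.1 ± 2.06 and 61.6 ± 2.39 CPM (SD, n = 3).

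In male precursors the same question gave 7276 changed genes, 3753 up and 3523 down, 3831 of them by at least 2-fold. Acp5 rose by 11.37 ± 0.25, Ctsk by 12.08 ± 0.49, Mmp9 by 12.10 ± 0.64, Dcstamp by 8.18 ± 0.20 and Nfatc1 by 3.91 ± 0.12, while Mrc1 fell by 5.95 ± 0.45 and C1qa by 4.94 ± 0.35. Calcr was at least 889-fold, Mt3 at least 3500.2-fold and Steap4 at least 861-fold higher with RANKL in males. There were 6239 genes called in both sexes, all 6239 in the same direction, 3229 up and 3010 down, where independent lists of these sizes would share 1006 and 885. Across all tested genes, which are not independent replicates, the log2 fold changes of the sexes had a Pearson r of 0.969 and a Spearman rho of 0.941. A further 636 genes were called in females only and 1037 in males only, which by itself does not show a difference between the sexes. In the submitters' own analysis, per the authors' deposited table, 5736 of 10255 genes in females and 6007 in males passed an adjusted p of 0.05, and 5609 and 5926 of them passed here too.

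**Figure D2:**
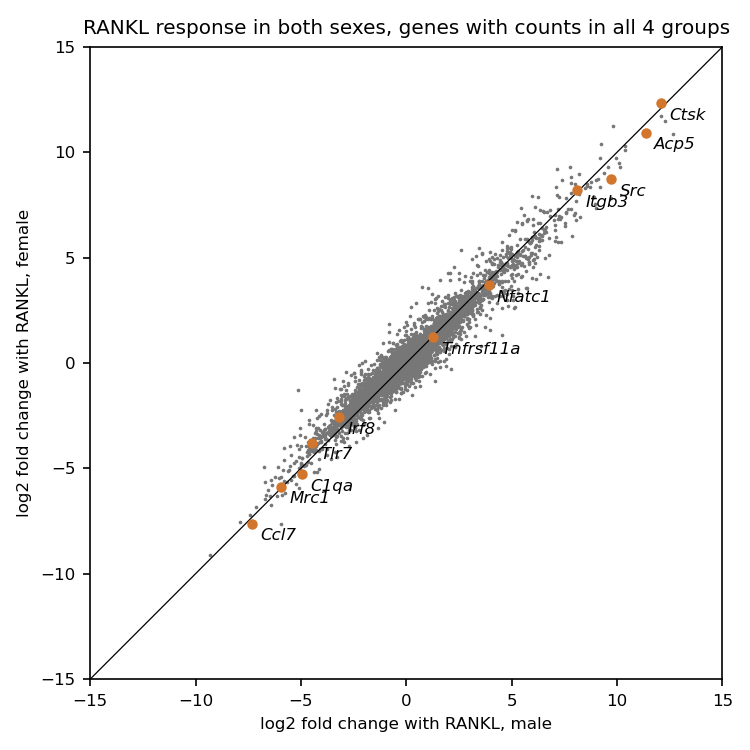
Log2 fold change with RANKL in males (horizontal) and females (vertical) for each tested gene with counts in all 4 groups (grey points), with named genes in orange and the line of equal change in black. The points lie along the line, among them Ccl7 at -7.31 in males and -7.62 in females and Ctsk at 12.08 and 12.32.

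Whether female and male precursors differed before RANKL was asked in the M-CSF libraries, and few genes passed with edgeR. Xist was higher in females, a ratio of 5198 to the 4 counts in males (95% counting interval 2029.7 to 19078). The Y genes Eif2s3y, a translation factor subunit, Ddx3y, an RNA helicase, and Uty, a histone demethylase relative, were lower in females by at least 887-fold, 872-fold and 319.5-fold, and Kdm5d, a histone demethylase, had 1 count in females and 1285 in males. With Gm29650, a Y-linked locus named after its values were seen (adjusted p 0.00247), these were all 6 genes that passed (edgeR, adjusted p below 0.05), 1 higher and 5 lower in females. DESeq2 called 16, 11 higher and 5 lower, and edgeR without a low count filter 12, 7 higher and 5 lower. None of the 6 lay on an autosome, and 478 genes had an unadjusted p below 0.05 where 662 were to be reckoned with by chance. Myeloperoxidase, Mpo, had 46.6 ± 11.5 CPM in females and 14.8 ± 1.88 in males (SD, n = 3), a log2 fold change of 1.65 ± 0.29 that did not pass (adjusted p 0.118; 2.22e-05 with DESeq2, and up to 0.642 over its alternatives). Itga1, a collagen-binding integrin subunit named here after its values were seen, had 1.27 ± 0.28 (adjusted p 0.458).

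Genes of the precursor state and of inflammation did not pass between the sexes in M-CSF. The log2 difference, female minus male, was 0.13 ± 0.12 for Csf1r, -0.03 ± 0.11 for Tnfrsf11a, 0.06 ± 0.11 for Runx1 and 0.04 ± 0.11 for Nfatc1. It was 0.38 ± 0.27 for Tnf, 0.74 ± 0.36 for Il1b, -0.02 ± 0.29 for the monocyte chemokine gene Ccl2, 0.07 ± 0.12 for the chemokine gene Ccl9 and 0.41 ± 0.15 for Nfkbia, an inhibitor of NF-kB (SE, n = 3 per group; adjusted p from 0.873 to 1). For 10474 of the 13236 genes the 95% interval of the difference lay within 2-fold in both directions. In 1114 genes, 8.42%, the 3 libraries of one sex all lay above those of the other, where chance gives 10%.

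As groups, 7 of the 30 tested lists passed in M-CSF with camera, and 0 of them with an estimated correlation (2 at an unadjusted p below 0.05) or with fry (1). The neutrophil and granule list was higher in females, with 15 of 15 members positive and a median log2 fold change of 1.45 (adjusted p 6.17e-17; adjusted p = 0.536 with an estimated correlation). It had 0 members past the edgeR test of all genes and 4 over the list alone. Female replicates 1 and 3 stood at a mean log2 CPM of 3.88 and 4.43 over the list, while female replicate 2 at 2.60 lay within the male range of 2.36 to 2.85. Without female replicate 3 the median was 0.75, with 14 of 15 positive (adjusted p 6.87e-10). Mitochondrial respiration genes were higher, 29 of 31 positive at a median of 0.13, such as Atp5b, an ATP synthase subunit, at 0.13 ± 0.10 (adjusted p 0.000272; adjusted p = 0.984 with an estimated correlation). Genes reported to escape X inactivation were higher, 9 of 12 positive at a median of 0.30 with 2 past over the list alone (adjusted p 0.00155; adjusted p = 0.536 with an estimated correlation). Without male M-CSF replicate 1 the adjusted p was 0.16. Ddx3x and Usp9x of that list had -0.18 ± 0.24 and -0.56 ± 0.30. Cell division was higher at a median of 0.11 (adjusted p 0.00263) and NF-kB at 0.04 (adjusted p 0.0434), both with adjusted p = 0.786 with an estimated correlation. The cell division call was lost without female M-CSF replicate 3 (adjusted p 0.0596), male replicate 1 (0.055) or male replicate 2 (0.197), and the NF-kB call without female replicate 2 (0.347) or male replicate 1 (0.468). Interferon-stimulated genes were lower in females, 33 of 35 negative at a median of -0.38 (adjusted p 0.00762; adjusted p = 0.984 with an estimated correlation). Cholesterol synthesis genes were lower, 17 of 18 negative at -0.18 (adjusted p 0.00706; adjusted p = 0.984 with an estimated correlation). The interferon direction turned without male M-CSF replicate 2, where the list was higher in females at a median of 0.27 with adjusted p 7.84e-06, and the cholesterol call was lost (adjusted p 0.507). Without female replicate 2 or 3 both calls were lost too (interferon 0.185 and 0.0516, cholesterol 0.273 and 0.0707). Other medians moved while the calls stood. Without male replicate 3 the median was -0.65 for interferon, -0.28 for cholesterol and 0.11 for NF-kB genes. Without female replicate 1 it was -0.33 for cholesterol, 0.17 for cell division and 0.09 for NF-kB genes, the last at 0.07 without male replicate 2. The number of lists fell to 4 without female replicate 2, female replicate 3 or male replicate 1.

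In the M-CSF+RANKL libraries the question was whether early osteoclasts of the sexes differed, and few single genes passed with edgeR. Itga1 was at 7.48 ± 2.52 CPM in females and 1.99 ± 0.269 in males (SD, n = 3), a log2 fold change of 1.91 ± 0.27 (adjusted p 0.0166) with all 3 female libraries above all 3 male. The libraries of either sex all lay above the other's in 1007 genes, 7.61%, a share no higher than chance gives. Xist was higher in females, a ratio of 8026 to the 3 counts in males (95% counting interval 2746 to 38919.9). Eif2s3y, Ddx3y, Uty and Kdm5d were lower in females by at least 1534-fold, 785-fold, 401-fold and 405-fold, and Gm29650 passed too (adjusted p 0.000469). These 7 genes, 2 higher and 5 lower in females, were all that passed, and 445 had an unadjusted p below 0.05. DESeq2 called 20, 15 higher and 5 lower, and edgeR without a low count filter 11, 6 higher and 5 lower. The Itga1 call was lost with only these 6 libraries in the fit (adjusted p 0.204), without female M-CSF+RANKL replicate 1 (0.0583) and without male replicate 1, 2 or 3 (0.0831, 0.217 and 0.118). Without female replicate 2 there were 12 genes in place of 7.

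No osteoclast gene passed between the sexes with RANKL. The difference, female minus male, was -0.11 ± 0.15 for Acp5, -0.04 ± 0.29 for Ctsk, -0.17 ± 0.11 for Nfatc1, -0.32 ± 0.19 for Calcr, -0.18 ± 0.39 for Mmp9 and -0.07 ± 0.13 for Dcstamp on the log2 scale (SE, n = 3 per group). Among inflammatory genes it was 0.56 ± 0.29 for Il1b, 0.35 ± 0.29 for Tnf and 0.19 ± 0.32 for Ccl2, and 0.57 ± 0.17 for lysozyme, Lyz2 (adjusted p 0.961). Clec4d, a C-type lectin receptor gene, had 0.55 ± 0.15 (adjusted p 0.795) and Tlr13 0.48 ± 0.24. For 10818 genes the 95% interval of the difference lay within 2-fold in both directions.

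As groups, 15 of 30 lists passed with RANKL, 10 higher and 5 lower in females; with an estimated correlation 1 did and with fry 0 (3 at an unadjusted p below 0.05). The X escape list held, with 9 of 12 positive at a median of 0.49 and 6 past over the list alone (adjusted p 2.91e-11, and adjusted p = 0.0474 with an estimated correlation). Granule genes were higher at a median of 1.33, with 15 of 15 positive and 8 past over the list alone (adjusted p 1.28e-21; adjusted p = 0.186 with an estimated correlation), and Mpo had 1.33 ± 0.29 (adjusted p 0.401). Female M-CSF+RANKL replicates 1 and 3 stood at a mean log2 CPM of 3.46 and 4.29 over the granule list, while female replicate 2 at 2.54 lay within the male range of 2.10 to 2.71. Without female replicate 3 the granule median was 0.71, with 14 of 15 positive (adjusted p 5.39e-13). Interferon-stimulated genes were higher in females here, 32 of 35 positive at 0.55 (adjusted p 5.85e-10; adjusted p = 0.524 with an estimated correlation), such as Parp14 at 0.44 ± 0.27 and Trim30a at 0.21 ± 0.25. Innate sensing genes were higher, 25 of 30 positive at 0.24 with 6 past over the list alone (adjusted p 5.54e-09; adjusted p = 0.209 with an estimated correlation). So were macrophage genes at 0.32 with 4 over the list alone (adjusted p 4.1e-06; adjusted p = 0.290 with an estimated correlation). Inflammatory cytokine genes were higher at 0.49 with 20 of 26 positive and 0 over the list alone (adjusted p 0.000475; adjusted p = 0.524 with an estimated correlation). All 32 cell division genes were positive, at 0.18, such as Mki67 at 0.24 ± 0.17 and Top2a at 0.26 ± 0.13 (adjusted p 1.6e-09; adjusted p = 0.209 with an estimated correlation). Osteoclast genes were lower in females, 25 of 27 negative at -0.15 (adjusted p 0.000197; adjusted p = 0.292 with an estimated correlation). Proton pump genes were lower too, 14 of 15 negative at -0.11, Atp6v1a at -0.21 ± 0.14 (adjusted p 0.00767; adjusted p = 0.524 with an estimated correlation). Without female replicate 3 the medians were 0.28 for interferon-stimulated (adjusted p 0.000653), 0.10 for macrophage (0.11), 0.03 for inflammatory (0.938) and -0.04 for proton pump genes (0.159). Without female replicate 2 they were 0.38 for innate sensing and -0.18 for proton pump genes, and without male replicate 3 it was 0.16 for innate sensing.

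Single libraries carried several of these list results with RANKL. Female M-CSF+RANKL replicate 3, with the highest mean log2 CPM of its treatment over the granule list, was among them. Without female M-CSF+RANKL replicate 3 the 15 lists became 6: the macrophage and proton pump calls were lost (adjusted p 0.11 and 0.159), and so were the inflammatory cytokine and complement calls (both adjusted p 0.938), with medians of 0.03 and 0.07. The inflammatory call was also lost without male M-CSF+RANKL replicate 1 (0.0849). Without male M-CSF+RANKL replicate 3 the osteoclast call was lost (adjusted p 0.177), and without male replicate 1 or female replicate 1 the proton pump call (0.308 and 0.0598). The complement list had passed at a median of 0.24 (adjusted p 0.00182; adjusted p = 0.386 with an estimated correlation). Also past the threshold were antigen presentation at 0.09 and stem and progenitor markers at 0.24, both higher, and cholesterol synthesis at -0.16, mitochondrial respiration at -0.06 and podosome genes at -0.10, all lower (adjusted p 0.0314, 0.0314, 0.0124, 0.0256 and 0.0314; with an estimated correlation adjusted p = 0.605, 0.209, 0.638, 0.693 and 0.524). Each of these 5 calls hung on several single M-CSF+RANKL libraries. The antigen presentation call was lost without female replicate 2 or 3 or male replicate 1 or 3 (adjusted p 0.326, 0.874, 0.121 and 0.177). The stem and progenitor call was lost without female replicate 1 or 3 or male replicate 1 or 2 (0.084, 0.119, 0.121 and 0.0581). The cholesterol call was lost without female replicate 2 or 3 or male replicate 2 (0.533, 0.275 and 0.997), and the mitochondrial call was lost without female replicate 1 or 3 or male replicate 1 (0.444, 0.938 and 0.931). The podosome call was lost without female replicate 2 or 3 or male replicate 3 (0.415, 0.0605 and 0.92). Other medians moved while the calls stood: without female replicate 1 to 0.19 for antigen presentation and -0.34 for cholesterol, and without female replicate 2 to -0.17 for mitochondrial genes. Without male replicate 2 the podosome median was -0.15, and without male replicate 3 it was -0.25 for cholesterol, -0.11 for mitochondrial and 0.14 for complement genes.

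Whether RANKL acted differently in the sexes was tested as an interaction, the female response minus the male one. No central osteoclast gene passed: the difference was -0.44 ± 0.31 for Acp5, 0.25 ± 0.60 for Ctsk, -0.21 ± 0.16 for Nfatc1, 0.11 ± 0.71 for Mmp9 and -0.13 ± 0.27 for Dcstamp. It was -0.18 ± 0.45 for Il1b, -0.03 ± 0.40 for Tnf, -0.51 ± 0.20 for Nfkbia, 0.05 ± 0.16 for Runx1 and -0.15 ± 0.18 for Csf1r. Among macrophage and sensing genes it was 0.40 ± 0.24 for Lyz2, 0.55 ± 0.33 for Tlr13 and 0.41 ± 0.21 for Clec4d. With edgeR 0 of 13236 genes passed, 260 had an unadjusted p below 0.05, and DESeq2 called 0 (259 at an unadjusted p below 0.05). For 9003 genes the 95% interval of the difference lay within 2-fold in both directions. In simulated data of this size 47.0% of planted 2-fold and 81.8% of 4-fold interactions were found. Before planting, the simulated genes had the same mean with and without RANKL. These shares therefore do not carry over to osteoclast genes that are nearly silent without RANKL.

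For 5 lists the response differed between the sexes by camera, each with adjusted p = 0.879 with an estimated correlation. Interferon-stimulated genes fell less in females, 35 of 35 positive at a median difference of 0.92 (adjusted p 1.41e-16), with Parp14, an ADP-ribosyltransferase, at 0.92 ± 0.37 and Trim30a at 0.50 ± 0.34. Innate sensing genes had a median of 0.33 with 25 of 30 positive (adjusted p 4.5e-06) and macrophage genes 0.16 with 21 of 24 positive (adjusted p 0.0036). Mitochondrial respiration genes rose less in females, 30 of 31 negative at a median of -0.18, such as Atp5b at -0.17 ± 0.15 (adjusted p 3.16e-09), and proton pump genes 13 of 15 negative at -0.13 (adjusted p 0.0392). With an estimated correlation or with fry 0 lists passed (0 at an unadjusted p below 0.05 with each), and 0 members of any of the 5 passed on their own, over all genes or over the list alone. The male M-CSF libraries enter this difference, and in 1 of them, replicate 2, the interferon list stood at a mean log2 CPM of 5.12 against 3.45 to 4.10 in the other 5 M-CSF libraries. Without it the median difference was 0.28 (adjusted p 0.00226). Without female M-CSF+RANKL replicate 3 it was 0.17 for innate sensing (adjusted p 0.00613) and -0.11 for mitochondrial genes (0.00025). Without female M-CSF+RANKL replicate 2 it was -0.33 for mitochondrial, -0.21 for proton pump and 0.40 for macrophage genes, the last at 0.38 without male M-CSF+RANKL replicate 2 and 0.26 without female M-CSF replicate 1. The macrophage call was lost without female M-CSF+RANKL replicate 3 (adjusted p 0.594), female M-CSF replicate 2 (0.0556) or male M-CSF replicate 1 (0.106). The proton pump call was lost without female M-CSF replicate 1 or 3, male M-CSF replicate 3, female M-CSF+RANKL replicate 3 or male M-CSF+RANKL replicate 1 (0.134, 0.0702, 0.457, 0.192 and 0.274). The 5 lists became 9 without female M-CSF replicate 3, 8 without male M-CSF replicate 2, 12 and 8 without female M-CSF+RANKL replicate 1 and 2, and 10 without male M-CSF+RANKL replicate 2.

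**Figure D3:**
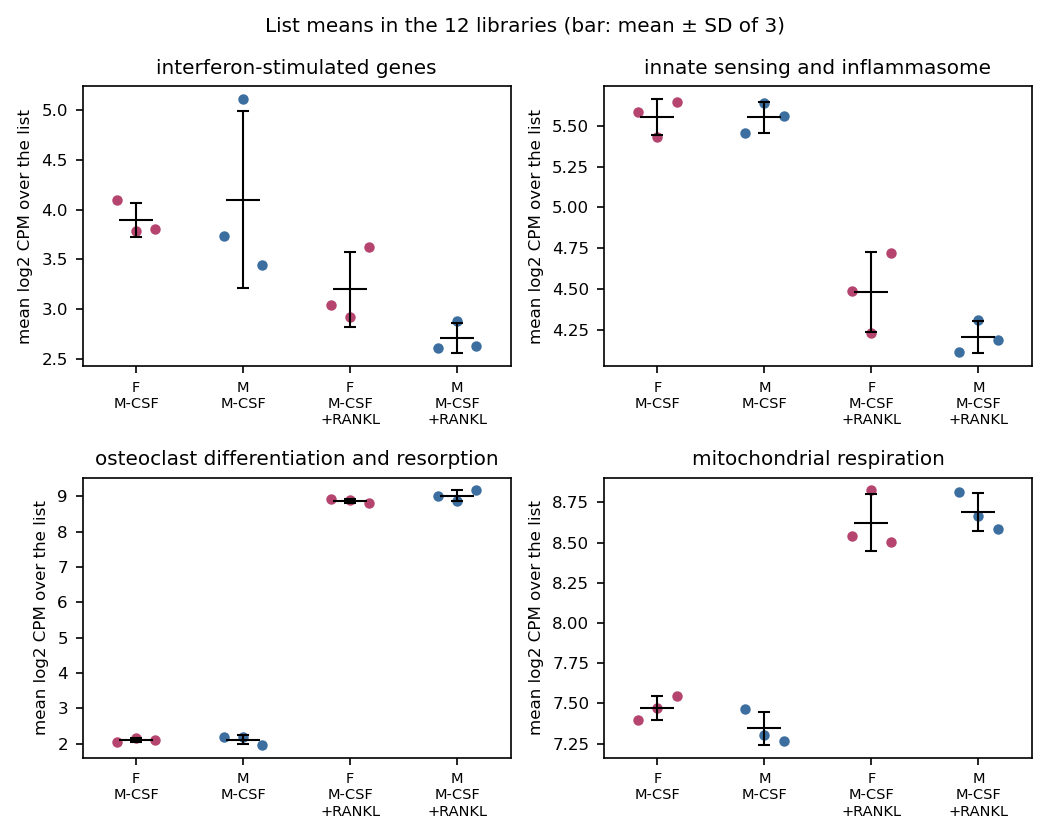
Mean log2 CPM over the genes of 4 lists in the 3 libraries (points) of each group, with F for female and M for male and bars for the mean and SD of 3 libraries. The interferon list reaches 5.12 in male M-CSF replicate 2, and the osteoclast list parts the libraries with RANKL from those without in both sexes.

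The sexes were last compared over the mean of both treatments, a comparison found in the authors' deposited table and added after the data were seen. Among the genes that parted females from males were enzymes of the primary granules of immature granulocytes. Ctsg, cathepsin G, was higher in females with a log2 fold change of 1.63 ± 0.20 (adjusted p 0.00263), Elane, neutrophil elastase, with 1.55 ± 0.19 (0.00304), Prtn3, proteinase 3, with 1.54 ± 0.20 (0.00436) and Mpo with 1.49 ± 0.21 (0.00703). Elane was at 23.5 ± 4.94 and 23.8 ± 11.4 CPM in the female M-CSF and M-CSF+RANKL groups and at 8.29 ± 0.522 and 7.88 ± 0.864 in the male ones (SD, n = 3). Itga1 was higher by 1.59 ± 0.19 (0.00263), and so were Plac8 at 1.36 (0.0239), Ly6c2, a monocyte surface antigen gene, at 1.22 (0.0495) and Sema4a, a semaphorin gene, at 0.51 (0.032). Ms4a3, a gene of granulocyte-monocyte progenitors named after its values were seen, was higher at 2.16 (0.0239). The X genes Eif2s3x, the partner of Eif2s3y, at 0.63 ± 0.10 (0.0268) and Pbdc1 at 0.49 ± 0.08 (0.0302) were higher, both known to escape X inactivation. With Xist and the Y genes these made 17 genes, 12 higher and 5 lower in females (672 at an unadjusted p below 0.05), against 47 with DESeq2, 41 higher and 6 lower. The authors' deposited table had 14, all 14 of them called here. Outside the 4 granule enzymes, Itga1, Xist and the Y genes, every call was lost without some single library. Without male M-CSF replicate 2 the adjusted p was 0.112 for Plac8, 0.219 for Ly6c2, 0.146 for Eif2s3x and Sema4a and 0.161 for Pbdc1, and without male M-CSF+RANKL replicate 2 it was 0.106 for Ms4a3.

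Of the lists, granule markers were higher in females with 4 of 15 past the edgeR test and 11 over the list alone (adjusted p 1.68e-27; adjusted p = 0.102 with an estimated correlation). X escape genes had 2 of 12 and 7 over the list alone (adjusted p 2.66e-09; adjusted p = 0.0804 with an estimated correlation). Also higher were cell division, innate sensing, inflammatory cytokine, macrophage, complement and mast cell lists (adjusted p 5.06e-08, 0.0011, 0.0017, 0.00408, 0.0279 and 0.0491; with an estimated correlation adjusted p = 0.290, 0.582, 0.678, 0.582, 0.630 and 0.290). Cholesterol synthesis was lower (adjusted p 0.00119; adjusted p = 0.772 with an estimated correlation). In all 9 lists passed, 0 with an estimated correlation and 0 with fry (5 at an unadjusted p below 0.05 with each). With counts summed over the treatments 7 passed, 6 of them among the 9, and the macrophage, innate sensing and complement calls were lost (adjusted p 0.527, 0.292 and 0.510). Without male M-CSF replicate 2 or female M-CSF+RANKL replicate 2 there were 14 lists, without female M-CSF+RANKL replicate 3 there were 5 and without both libraries of female replicate 3 there were 3. Interferon-stimulated genes did not pass, at a median of 0.05 with 22 of 35 positive (adjusted p 0.16). Without male M-CSF replicate 2 they were higher in females at a median of 0.43 with 34 of 35 positive (adjusted p 2.28e-17), and they also passed without female or male M-CSF+RANKL replicate 2 (0.0166 and 0.0314). Without female M-CSF+RANKL replicate 3 the macrophage, inflammatory and complement calls were lost (0.224, 0.498 and 0.877), and without male M-CSF+RANKL replicate 1 the last 2 of them (0.0607 and 0.0966). The complement call was lost without male M-CSF replicate 3 (0.0684) and the cholesterol call without male M-CSF+RANKL replicate 2 (0.0679). The mast cell call was lost without replicate 1 of any group, male M-CSF replicate 3 or female M-CSF+RANKL replicate 3 (0.0768 to 0.138). Libraries of the same sex and replicate number moved together, so the 2 treatments are not independent. With their counts summed, 3 libraries against 3, Ctsg kept its fold at 1.63 but not its call (adjusted p 0.105), like Itga1 (0.142), Elane (0.142) and Mpo (0.266), and 6 genes passed. Without both libraries of male replicate 2 there were also 6 genes, without those of male replicate 3 there were 11 and without those of female replicate 2 there were 27. Without female M-CSF replicate 1, male M-CSF replicate 1 or male M-CSF+RANKL replicate 2 alone there were 11 each.

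**Figure D4:**
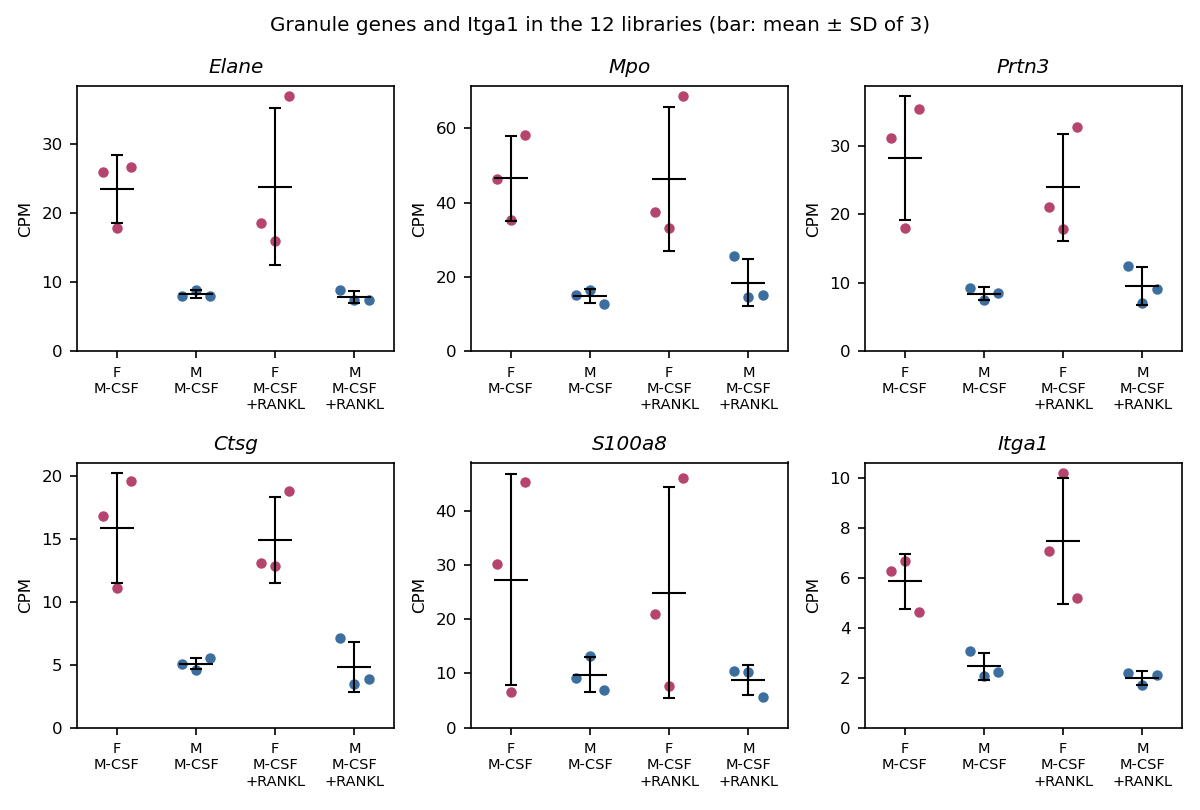
CPM of Elane, Mpo, Prtn3, Ctsg, S100a8 and Itga1 in the 3 libraries (points) of each group, with F for female and M for male and bars for the mean and SD of 3 libraries. All 6 female libraries lie above all 6 male libraries for Elane, Mpo, Prtn3, Ctsg and Itga1, while for S100a8 female replicate 2 lies at 6.50 and 7.72 CPM, within the male range. Of all 13236 tested genes 26, or 0.196%, part the sexes without overlap in either direction, a share no higher than chance gives for 6 against 6.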

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

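The tests of explanations and the regroupings in this part were chosen after the results were seen, while the tests of the difference in response between the sexes were planned.

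For 5 gene lists the response to RANKL differed between females and males by the camera test of the difference itself. These were interferon-stimulated genes (adjusted p 1.41e-16), mitochondrial respiration (3.16e-09), innate sensing and inflammasome genes (4.5e-06), macrophage and monocyte identity (0.0036) and the vacuolar proton pump (0.0392), each with adjusted p = 0.879 with an estimated correlation. Regrouping the 6 pairs of libraries of the same sex and replicate number, 8 of 10 splits, the real one included, gave 5 or more lists, with up to 9 in the others, and 10 splits are too few for a share under 0.05. For single genes the count was 0 with edgeR (260 at an unadjusted p below 0.05) and 0 with DESeq2 (259), and all 10 splits gave 0 with edgeR.

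Granule enzyme genes (Elane, Mpo, Prtn3 and Ctsg) were higher in female libraries of both treatments. Carried-over mature neutrophils were examined as a source, although these are enzymes of immature granulocytes and the sort took cells with little or no CD11b. The folds argue against such cells as the whole cause. The mean log2 CPM of S100a8, S100a9, Camp, Ltf and Ngp served as a covariate. With it the 4 enzyme genes kept log2 fold changes of 1.21 to 1.43, Elane at 1.27 ± 0.13 from 1.55 ± 0.19. In this edgeR fit 4 of 4 passed (Elane adjusted p 0.000889). It took all 12 libraries as independent, although the 2 treatments of a sex and replicate number moved together, and it was not run on summed counts. This neutrophil score is not limited to mature cells, as Camp, Ltf and Ngp are also genes of earlier stages. Ly6g, Retnlg and Cxcr2 of the granule list had 5, 5 and 43 counts over all libraries and were not tested. The score was 1.11 and 1.48 in female replicate 2, below the 3 male libraries of the same treatment, where S100a8 was at 6.50 and 7.72 CPM and the enzyme score lay above all male libraries. The values also argue against a single replicate number of one sex, as the lowest log2 fold change without any such pair of libraries was 1.20 (Mpo, without female replicate 3), though all 4 calls were lost without both libraries of male replicate 2 (adjusted p 0.0571 to 0.0934), those of Mpo and Prtn3 without male replicate 3 (0.096 and 0.058), and all 4 on summed counts (0.105 to 0.266). A higher share of granulocyte-monocyte progenitors in the female cells stays open, and so does a difference between the sexes within cells, which was not tested. The stem and progenitor list had a camera adjusted p of 0.0705 (0.0276 to 0.0481 without female replicate 2 or male replicate 3 of either treatment or male M-CSF replicate 2). It holds stem and progenitor genes in general, so it cannot measure the share of granulocyte-monocyte progenitors in particular. With an estimated correlation the stem and progenitor list did not pass for the mean of both treatments.

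Interferon-stimulated genes were lower in female than male M-CSF libraries, at a median log2 difference of -0.38 (adjusted p 0.00762; adjusted p = 0.984 with an estimated correlation). A difference shared by the male libraries is argued against, since 1 of the 3 lay above all female M-CSF libraries, replicate 2 at a mean log2 CPM of 5.12, with the others at 3.74 and 3.45 against 3.79 to 4.10 in females. Without male replicate 3 the median was -0.65 and without male replicate 2 it was 0.27, so that this library alone is a candidate explanation of the direction. The difference in RANKL response had a median of 0.28 without it (adjusted p 0.00226; 4.16e-40 to 0.941 over the alternatives). What set the library apart was not tested.

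In M-CSF+RANKL libraries, macrophage, innate sensing and inflammatory lists were higher and osteoclast and proton pump lists lower in females (with an estimated correlation adjusted p = 0.290, 0.209, 0.524, 0.292 and 0.524), which may come from 1 library or from a smaller response in all female cultures. Without female M-CSF+RANKL replicate 3, 2 of the 5 lists remained past the threshold in the same direction, innate sensing (adjusted p 0.000103; 1.94e-15 to 0.360 over the alternatives) and osteoclast genes (0.0168; 1.79e-08 to 0.360), and that library also had the highest neutrophil score of its treatment, 4.41 against 1.48 to 2.99. Over 1732 genes raised and 1430 lowered at least 2-fold by RANKL in both sexes, the mean log2 CPM of the raised minus that of the lowered changed by 4.70, 4.73 and 4.39 from the female M-CSF to the M-CSF+RANKL library of the same number, and by 5.02, 4.76 and 4.92 in males. These genes were picked by their RANKL response in the same libraries and may include members of the 5 lists, so this measure is not separate evidence. All 3 female responses lay below all male ones, which a smaller response in all female cultures would give, though the closest lay 0.0388 apart, the exact two-sided permutation p of 0.1 is the smallest that 3 against 3 allow, and in the M-CSF+RANKL libraries alone 2 of 3 lay below. Whether female replicate 3 alone carries the lists cannot be told apart from this with 3 libraries per group, and a difference between the sexes stays open as a hypothesis.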

How the results depend on the processing

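The tests on the authors' filtered genes and all those on the mean of both treatments were chosen after seeing the data. The cause of the changes below was not tested, except where fewer genes or libraries enter by construction.

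DESeq2 size factors and the authors' filtered genes moved no count of genes or lists by over 1.5 times. RANKL called 6293 to 6612 genes in females and 6675 to 6984 in males with 1 library left out, and 3442 and 3831 of at least 2-fold. With an estimated correlation 2 lists passed in each sex for RANKL, 1 for the sexes in M-CSF+RANKL, and 0 for the sexes in M-CSF, for the response difference and for the mean of both treatments (2, 0 and 5 lists at an unadjusted p below 0.05). With fry 0 lists passed in the 4 comparisons that involve sex (1, 3, 0 and 5 at an unadjusted p below 0.05 for M-CSF, M-CSF+RANKL, the response difference and the mean). For RANKL 22 of 30 lists passed with fry in each sex, 7 higher and 15 lower. In females 14 and in males 15 of these were also called with camera. In these comparisons 51.9% and 55.0% of all tested genes were called. Without Xist, Tsix and the Y genes Ddx3y, Eif2s3y, Kdm5d and Uty, 1 gene was left in M-CSF and 2 in M-CSF+RANKL, with the Y-linked Gm29650 still counted in each. Without a low count filter 12 and 11 genes passed there, and 16 lists for the mean of both treatments. With only the 6 libraries compared 10 genes passed in M-CSF. DESeq2 called 16 genes in M-CSF, 20 in M-CSF+RANKL and 47 for the mean, with 10 lists for the response difference and 16 for the mean. Summed counts gave 6 genes for the mean.

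Leaving out libraries gave 4 lists (without female M-CSF replicate 2) to 9 (female 1) in M-CSF. In M-CSF+RANKL it gave 6 (female M-CSF+RANKL replicate 1) to 12 genes (female 2) and 6 (female 3) to 14 lists (female 2). It gave 4 (female M-CSF replicate 2) to 12 lists (female M-CSF+RANKL replicate 1) for the response difference. For the mean it gave 6 genes (both libraries of male replicate 2) to 27 (female 2), and 3 lists (female 3) to 14 (male M-CSF replicate 2).

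For some lists the direction of the camera statistic turned, with these ranges of adjusted p without 1 library. In M-CSF interferon-stimulated genes ranged from 3.36e-12 to 0.185 and turned without male replicate 2 (7.84e-06). In M-CSF+RANKL inflammatory genes (5.43e-10 to 0.938) and complement genes (3.39e-05 to 0.938) lost their calls without female replicate 3, cholesterol synthesis (3.05e-07 to 0.997) without male replicate 2 and podosome genes (0.00341 to 0.920) without male replicate 3. There the camera statistic changed sign at the highest p of each range, with medians of 0.03, 0.07, -0.0148 and 0.00147, so these lists moved to no detectable difference. For the response difference inflammatory genes (1.19e-05 to 0.912) and granule genes (0.00735 to 0.964) turned without female M-CSF+RANKL replicate 3 (0.0306 and 0.00735) and cholesterol synthesis (0.0129 to 0.845) without female M-CSF+RANKL replicate 1 (0.0342).

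With the replicate number as a block within each sex, where the numbers pair the libraries, RANKL called 8014 and 8356 genes and 15 and 16 lists, and the response difference 0 genes (658 at an unadjusted p below 0.05, with DESeq2 also at 0 but run without the block) and 6 lists. The gained lists were repressors in males (adjusted p 0.0355) and X escape genes for the difference (0.0232). Between the sexes the numbers do not pair libraries throughout (correlations of -0.498 to 0.521 for the same number and treatment). Another matching, picked after the values were seen, had positive correlations within and across treatments. They were 0.202 to 0.373 for female 1 with male 2 and 0.200 to 0.729 for female 2 with male 1. For female 3 with male 3 they were 0.115 to 0.521. The block by number follows this matching for replicate 3 only. Variation shared between the sexes in this way was not fully modelled in any test here. In comparisons of the sexes the block by number gave 8 and 9 genes and 6 and 14 lists in M-CSF and M-CSF+RANKL, and 26 genes and 8 lists for the mean, without the calls of NF-kB (0.0506), podosome (0.0546) and mast cell lists (0.0736). The block changed no other call of a list or named gene.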

Other observations

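The tests of X dosage and of other splits in this part were chosen after the results were seen.

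RANKL also moved genes of cell types that the sort should have removed or that share genes with osteoclast precursors. B cell markers fell, 4 of 4 tested genes in females and 3 of 4 in males, with the same counts adjusted over the list alone (camera adjusted p 0.0208 and 0.0272; adjusted p = 0.125 and 0.122 with an estimated correlation; 0.0515 in males without a low count filter). Among them were Ighm, the heavy chain of immunoglobulin M, with log2 fold changes of -3.18 in females and -4.08 in males, and Bank1, a B cell adaptor, with -2.79 and -3.04. Il7r, the interleukin 7 receptor gene on the T and NK list, had -3.42 and -3.87, while Trac, the constant region of the T cell receptor alpha chain, was at least 31.7-fold and 33.2-fold higher with RANKL. That list had 1 of 4 genes up and 1 down in each sex and did not pass (adjusted p 0.706 and 0.793, in the lower direction while the medians were 0.21 and 1.04). Of 5 mast cell genes 3 rose in each sex and 1 fell in males (adjusted p 0.272 and 0.284). Gata2, a transcription factor of progenitors and mast cells, had ratios of 33.9 (95% counting interval 14.3 to 105) and 30.0 (13.6 to 82.8). Both tested eosinophil genes rose, Ccr3, a chemokine receptor, by 2.85 and 2.81 on the log2 scale. Of 7 endothelial genes 2 rose and 3 fell in females and 1 rose and 3 fell in males (adjusted p 0.212 and 0.273), Kdr, a VEGF receptor, with -3.16 and -2.74 and Cdh5 with -2.52 and -2.90. Of 12 dendritic cell genes 3 rose and 4 fell in each sex (adjusted p 0.911 and 0.873), the transcription factor genes Batf3 with -2.84 and -2.01 and Zbtb46 with 1.67 and 1.67. The means of 0.14 and 0.16 lay opposite to the medians of -0.13 and -0.57. Megakaryocyte markers had 2 of 4 up and 2 down in females and 1 up and 2 down in males (adjusted p 0.417 and 0.423, in the higher direction while the medians were -1.08 and -0.98). Of 10 stem and progenitor genes 2 rose and 1 fell in each sex (adjusted p 0.955 and 0.892), Cd93 with -3.55 and -4.17. Of 2 stromal genes 1 fell in each sex, Kitl with -2.61 and -2.90, and 0 erythroid genes were tested. Granule genes had 2 of 15 down in each sex, Mmp8, a neutrophil collagenase, with -1.66 and -1.94 (adjusted p 0.556 and 0.555).

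Antigen presentation, stress and hormone lists went both ways with RANKL and did not pass. Of 21 antigen presentation genes 3 rose and 6 fell in females and 2 rose and 7 fell in males (adjusted p 0.452 and 0.42), Cd40, a costimulatory receptor, with -2.42 and -2.79. Of 22 glycolysis and hypoxia genes 16 fell in females and 10 in males, and 3 rose in each (adjusted p 0.08 and 0.201; 0.0177 in females without female M-CSF replicate 1, and 0.00215 and 0.0209 without a low count filter). Slc16a3, a lactate transporter, had -1.18 and -1.12 and Vegfa, a growth factor of blood vessels, 1.72 and 1.28. Of 20 immediate early and stress genes 4 rose in each sex and 6 and 7 fell (adjusted p 0.218 and 0.207), Hmox1, haem oxygenase, with -3.10 and -3.34 and Atf3, a stress transcription factor, with -3.40 and -3.95. Of 7 sex hormone genes 1 rose and 3 fell in females and 2 rose and 4 fell in males (adjusted p 0.706 and 0.666), Esr1, the estrogen receptor alpha gene, with -1.46 and -2.07 and Srd5a1, a steroid reductase, with 2.10 and 2.41. The means of 0.04 and 0.02 lay opposite to the medians of -0.25 and -0.55. Of 5 Runx family genes 1 rose and 2 fell in each sex (adjusted p 0.58 and 0.708), Cbfb, the partner of Runx proteins, with -0.73 and -0.51. Of 19 X-linked immune genes 7 rose and 8 fell in females and 8 each in males (adjusted p 0.275 and 0.217), and in males the median of 0.03 lay opposite to the mean of -0.78. Of 12 X genes with reported escape 1 rose in each sex and 1 fell in males (adjusted p 0.911 and 0.785), Kdm5c, a histone demethylase, with 0.86 and 0.73.

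For the 412 tested X genes outside the escape list, female libraries at the level of 2 active copies would have a log2 difference near 1, and the median was -0.0246 over the mean of both treatments, which argues against it.

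For the counts above, 10 splits of 6 libraries, or of 6 pairs for the mean of both treatments, are too few for a share under 0.05. In M-CSF the sexes gave 6 genes against at most 4 in other splits and 7 lists against 8, and 1 and 3 of the 10 splits gave as many. Xist and the Y genes part the sexes by construction: without Xist, Tsix, Ddx3y, Eif2s3y, Kdm5d and Uty the count was 1 against 4 in M-CSF, 2 against 0 in M-CSF+RANKL and 12 against 24 for the mean of both treatments. These counts for the sexes still include Gm29650, the Y-linked locus. Outside the X and Y chromosomes the sexes gave 0, 1 and 9 genes in the same order. In M-CSF+RANKL the sexes gave 7 genes against 0 and 15 lists against 13, with 1 split each. RANKL gave 6875 genes in females and 7276 in males against 0 in other splits, and 15 lists in each against 14 and 17, with 1 and 2 splits giving as many lists. The other splits put libraries with and without RANKL in the same group, so the RANKL effect enters their spread. Their 0 genes are therefore no reference for chance. Among the 4 splits that part all 3 pairs within a sex, the others gave 0 genes and at most 12 lists in females and 14 in males. The mean of both treatments gave 17 genes against 24 and 9 lists against 12, with 2 and 5 splits giving as many. At an unadjusted p below 0.05 (edgeR) the mean gave 672 genes, against 165 to 3357 in the splits that mix the sexes.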
